A study of Homo sapiens with 8 samples.

How the data were processed

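RNA from DAOY cells, an established human medulloblastoma line, was measured on 8 Illumina bead arrays. Per the labels, 5 arrays came from numbered stable lines carrying an MXD3 expression plasmid, 2 from numbered stable lines carrying the vector alone and 1 from the parental cells. The stable lines were selected and kept in 800 µg/ml G418, per the labels' protocols, which name no selection for the parental cells. Total RNA was purified on Qiagen columns, its quality was read on an Agilent Bioanalyzer, and biotin-labelled cRNA was made with an Ambion kit, per the labels' protocols. The labels do not say whether the numbered lines were separate clones or when each was grown, so the p-values measure the spread between these samples.

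The deposited non-normalized table gives an intensity for 22184 probes on each array, on a linear scale, and the deposited detection p-value of each probe beside it. BeadStudio is named in the submitters' processing notes, with no version. The lowest intensity of an array lay between 88.4 and 118, so no background had been subtracted. A second deposited table, the series matrix, holds intensity values that were a straight line of the first table in each array, to within 0.0121. An array's own line left residuals up to that size, against at least 12500 for another array's. The series matrix values shared a mean of 1363 on every array, had medians from 87.5 to 98.7 and fell below 0 for 2996 to 3304 probes, so the authors subtracted a background constant per array and scaled each array by 1 factor. Its scale is linear. How the constants were chosen is not given in the sources used here.

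The mean intensity of an array ran from 1346 to 1797, and 60.5% to 64.0% of its probes had a detection p-value below 0.05. Pairs of arrays correlated at r = 0.969 to 0.987 across genes on the log2 scale. The SD of the log2 difference between arrays was at least 0.395 in all 28 pairs, so no array was a copy of another. The number of arrays limits the precision: 5 lines against 2 or 3.

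Intensities were background-corrected with negative controls inferred from the detection p-values, quantile-normalized and put on the log2 scale (neqc in limma 3.58.1, offset 16, R 4.3.3). A probe was kept if its detection p-value was below 0.05 on at least 2 arrays. Of the 22184 probes, 19715 named 1 gene, none named several, and 2469 had no symbol in the annotation table used here. The probe with the highest mean log2 intensity stood for its gene, which left 12162 genes, 1937 of them with more than 1 probe on the array. Symbols came from the platform annotation, checked through Entrez IDs against the RefSeq gene table of assembly GRCh38.p14. The IDs of 20 probes were not in that table. Where a gene was below detection on all arrays of a group, the fold is given as "at least", set against the lowest detected signal of each array in that group.

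Groups were compared with lmFit and eBayes in limma, two-sided, with Benjamini-Hochberg adjustment over all 12162 genes and a threshold of 0.05. The MXD3 lines were compared with the vector lines in a fit of 3 groups, and with the vector and parental lines together in a fit of 2 groups. The 3-group fit also gave the MXD3 and the vector lines against the single parental array, which was assumed to vary like the other groups.

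Before the data were examined, 36 gene lists were fixed from textbook knowledge. They cover MYC and its partners, the cell cycle, cell death, developmental pathways, matrix and adhesion, markers of other cell types, inflammation, metabolism, stress and housekeeping complexes. All 36 had at least 5 measured genes. Each was tested with camera at a preset correlation of 0.01, adjusted over the lists. A list is said to be called or not called by this test. Camera with an estimated correlation and the 2 tests of fry stand beside it, one for a shift in 1 direction and one (mixed) for changes in either direction. Mean and median of a list and the direction of its test differed in sign for 7 lists against the vector lines and 5 against the vector and parental lines, none of them called. A list's value in an array is the mean over its genes of the log2 intensity minus the gene's mean over all 8 arrays. Two-sided exact permutation tests on these values have 56 splits of 5 against 3, with a smallest p of 0.0179.

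The rule for the genes named was also fixed before the data were examined. It takes MXD3 in every array, and up to 12 genes per direction and comparison past the threshold whose MXD3 arrays all lie on one side of the controls. Where none passes in a direction, it takes the 5 with the smallest p, given as values. It also takes up to 4 members of each list past the threshold, or up to 2 with the smallest p, given as values. For the parental comparisons it takes up to 5 genes per direction past the threshold, and symbols starting LOC are not named. The rule named 90 genes. Another 26 list members (PES1, RRS1, PTMA, FBL, NOLC1, NOP56, NME1, MLX, MAX, LIF, IL6, CCL2, IL1A, TNF, RPL7, RPL14, RPL13, MKI67, TPX2, KIF11, SMO, TAP2, HLA-F, COL8A1, COL18A1 and COL16A1) were named after their values were seen. The count of genes whose groups do not overlap was also added after the data were seen.

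The fits were tested on 20 simulated sets of 12162 genes with 200 changed. Against vector and parental lines, 4.93% of genes changed by 0.5 on the log2 scale were recovered, 61.4% of those changed by 1 and 95% of those changed by 2. Against the vector lines these shares were 1.49%, 39% and 90%. Of the calls, 5.26% and 5.05% were false. Camera was simulated for the comparison with vector and parental lines only, where it called 2 lists in the 20 simulated sets of 36 with none shifted, and recovered a list shifted by 0.3 in all 20. These simulations gave the genes independent noise.

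The alternatives tried were normexp without negative controls (offset 50), no background correction, median scaling, the series matrix values (floor 16), no filter, detection p below 0.01 on all 8 arrays, every probe tested on its own, eBayes with trend and robust settings, array weights, each array left out, the line number as a block, the 7 stable line arrays alone, and a fold of at least 1.5 as a further threshold. A chip or slide block was not run, because the tables used here name no chip. The 1431 detected probes without a symbol were tested apart. Figures were drawn with matplotlib 3.10.9.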

Results

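Gene expression was measured in DAOY medulloblastoma cells that stably carried MXD3, in lines with the empty vector and in the parental cells. MXD3 encodes a member of the MXD family of transcription factors, which pair with MAX and repress genes that MYC with MAX activates. The series held 5 MXD3 lines, 2 vector lines and 1 parental sample, each on 1 array. Detection p-values were below 0.05 for 13432 to 14199 of 22184 probes per array. The design asks how the MXD3 lines differed from the vector lines and from the parental cells.

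MXD3 itself was read by 1 probe. Its log2 intensity was 7.47, 7.22, 6.98, 8.08 and 6.18 in MXD3 lines 1 to 5, 6.93 and 6.71 in the vector lines and 6.59 in the parental cells. The mean was 7.19 ± 0.70 (SD, n = 5) in the MXD3 lines and 6.74 ± 0.17 (SD, n = 3) in the controls. The log2 difference of 0.44 gave p = 0.339 in the two-sided exact permutation test, and against the vector lines alone the difference of 0.37 gave p = 0.524, also exact. MXD3 lines 1 to 4 lay above all controls, and the array labelled MXD3 line 5 lay below all of them. Whether the probe lies in the part of the transcript that the transgene carries was not analysed here.

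Among the 11 measured members of the MYC, MAX and MXD family, MYC and MNT had the highest values in the MXD3 lines relative to controls. MYC was 12.67 ± 0.20 (SD, n = 5) against 12.12 ± 0.12 (SD, n = 3), a log2 difference of 0.55 ± 0.15 (SE). MNT, which encodes another MAX partner that represses transcription, differed by 0.51 ± 0.14 (SE). Both lay above all 3 controls in 5 of 5 MXD3 lines, and both passed limma's test when adjusted over the list alone (adjusted p = 0.0225 each). MLX differed by -0.42 ± 0.14 and MAX by -0.51 ± 0.19 (SE), and neither passed. The 2 other probes of MAX gave -0.29 and 0.14, and against the vector lines alone its 3 probes gave -0.26, -0.29 and 0.25. Over all genes tested the adjusted p was 0.288 for MYC and for MNT. Camera did not call a shift of the family as a whole in 1 direction (adjusted p = 0.908), while the mixed test of fry, for changes in either direction, passed (adjusted p = 0.00948). Against the vector lines alone MYC differed by 0.48 ± 0.17 and MNT by 0.44 ± 0.15, no member passed over the list alone (smallest adjusted p = 0.109), and the mixed test did not pass (adjusted p = 0.178).

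**Figure D1:**
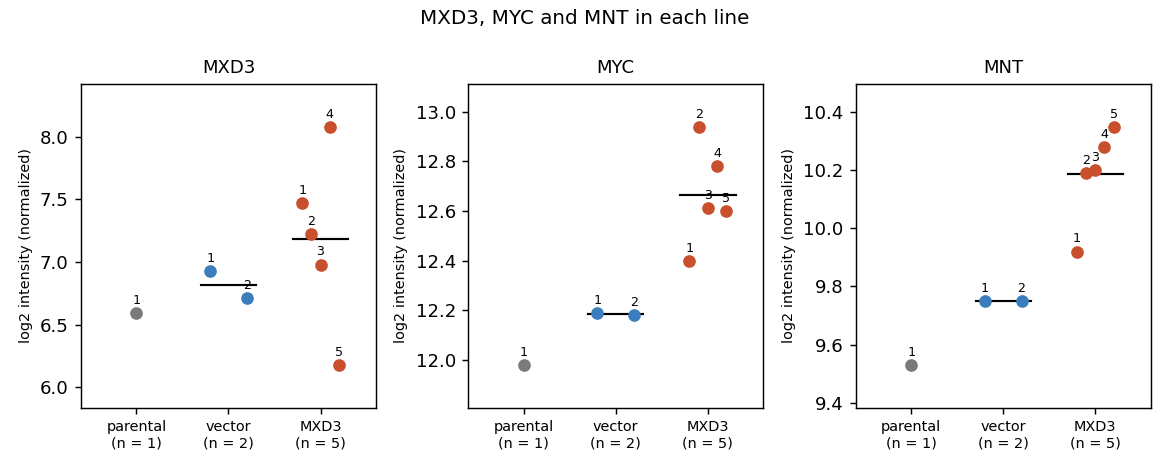
Normalized log2 intensity of MXD3, MYC and MNT in each line, by group; points are single arrays numbered by line and horizontal bars are group means. MXD3 ranged from 6.18 to 8.08 among the MXD3 lines, while MYC and MNT lay above all 3 controls in each of the 5 MXD3 lines.

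MYC target genes were lower in the MXD3 lines. Of the 30 measured members, 28 had lower means in the MXD3 lines than in the vector and parental lines, with a mean log2 difference of -0.32, and camera called the list (adjusted p = 4.23e-09), though not with an estimated correlation (adjusted p = 0.652). None of the 30 passed over all genes tested. In limma's test adjusted over the list alone 9 passed, all lower and all close to the threshold (adjusted p = 0.0443 to 0.0472). Of these 9, NOP16 (-0.58 ± 0.13 SE), MRTO4 (-0.60 ± 0.16), PES1 (-0.58 ± 0.16) and RRS1 (-0.55 ± 0.16) encode factors of ribosome assembly. FBL (-0.58 ± 0.18), NOP56 (-0.47 ± 0.15) and NOLC1 (-0.57 ± 0.18) encode proteins of small nucleolar RNA complexes or the nucleolus, and PTMA (-0.55 ± 0.17) and NME1 (-0.46 ± 0.15) are prothymosin alpha and a nucleoside diphosphate kinase.

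Against the vector lines alone, 29 of the 30 MYC targets had lower means, with a mean log2 difference of -0.32 (adjusted p = 1.56e-08, camera). With an estimated correlation this call did not hold (adjusted p = 0.855). No member passed there, over all genes or over the list alone. Per array, all 5 MXD3 lines had a list mean below those of the 3 controls, at 0.05, -0.18, -0.01, -0.14 and -0.31 in lines 1 to 5 against 0.11 to 0.28. The exact permutation test of these means gave p = 0.0357, and 0.321 after adjustment over the 36 lists. The smallest p this test can give is 0.0179, so 1 list by itself could not pass that adjustment. Across the MXD3 lines the list mean did not follow the MXD3 probe. Line 5 had the lowest list mean and the lowest MXD3 reading (6.18). Line 1 had the highest list mean at an MXD3 reading of 7.47, and line 4 the highest MXD3 reading (8.08) at a list mean of -0.14. Whether that probe reads the transgene was not analysed.

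**Figure D2:**
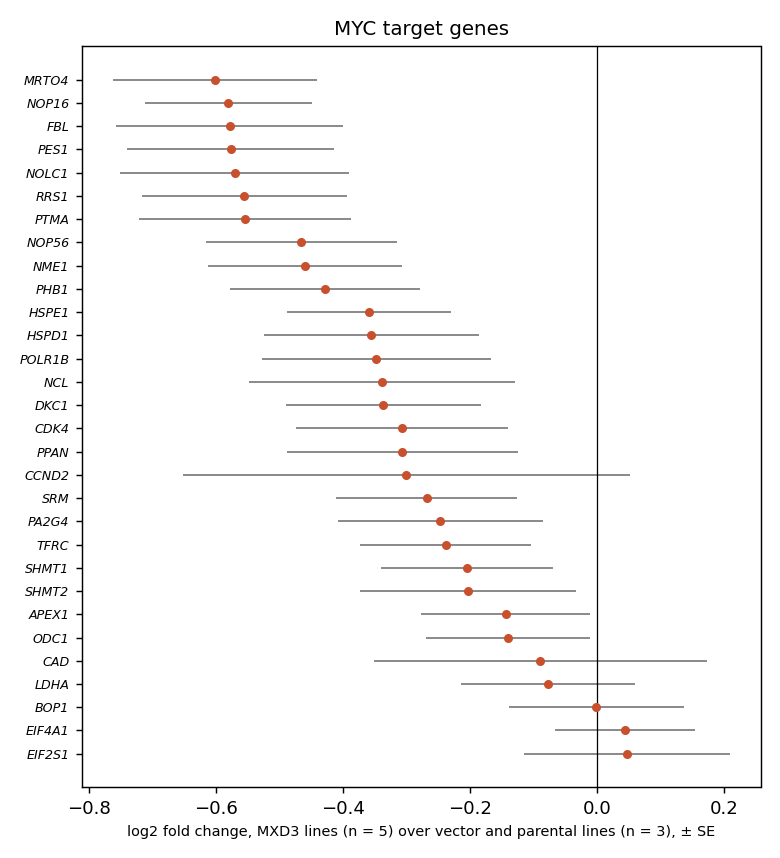
Log2 fold change of each of the 30 measured MYC target genes, MXD3 lines (n = 5) over vector and parental lines (n = 3); points are estimates, bars their standard errors, and the vertical line marks no difference. The values lie below 0 for 28 genes and reach -0.60 for MRTO4.

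Cytosolic ribosomal protein genes were shifted the same way by a smaller amount. Of 35 measured members, 31 had lower means in the MXD3 lines in both comparisons. The mean log2 difference was -0.16 against the vector and parental lines (adjusted p = 0.00317, camera) and -0.18 against the vector lines (adjusted p = 0.00161). The calls did not hold with an estimated correlation (adjusted p = 0.652 and adjusted p = 0.855). RPS7 differed by -0.57 ± 0.14 (SE), RPS15 by -0.83 ± 0.29, RPL7 by -0.41 ± 0.14, RPL14 by -0.36 ± 0.16 and RPL13 by -0.29 ± 0.13. None of the 35 passed, over all genes or adjusted over the list alone. Without vector line 2 the calls ended (adjusted p = 0.0991 and 0.131). The list means of all 5 MXD3 lines lay below those of the 3 controls (exact permutation p = 0.0357, adjusted 0.321, with the same limit as for the MYC targets). The separation was narrow, with MXD3 line 1 at 0.023 and vector line 1 at 0.035.

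Cytokine and chemokine genes were higher in the MXD3 lines, but the lines and the controls were each divided. Of 20 measured members, 16 had higher means in the MXD3 lines, with a mean log2 difference of 0.71 against vector and parental lines (adjusted p = 0.00475, camera) and 0.64 against vector lines (adjusted p = 0.00888). With an estimated correlation neither call held (adjusted p = 0.652 and adjusted p = 0.855). The interleukin gene IL1B differed by 3.13 ± 0.83 (SE), LIF by 1.80 ± 0.54, IL6 by 1.62 ± 0.67, IL1A by 1.34 ± 0.55, CCL2 by 1.28 ± 0.48 and TNF by 1.26 ± 0.49. IL1B and TNF were each detected in all 5 MXD3 lines and in 1 of the 3 controls. Against the vector lines alone TNF differed by 0.83 ± 0.51. None of the 20 passed, over all genes or adjusted over the list alone. The list mean was 0.42 to 0.48 in MXD3 lines 2 to 5 and -0.41 in MXD3 line 1. It was 0.39 in vector line 1, -1.14 in vector line 2 and -0.59 in the parental cells. Without vector line 2 the mean difference was 0.37 (adjusted p = 0.31) and, against the remaining vector line, -0.13 (adjusted p = 0.902). Without it IL6 was 0.98, IL1A 0.87 and CCL2 0.65 against vector and parental lines. Without vector line 1 these means were 1.14 and 1.41. CXCL12, a chemokine gene read by 3 detected probes, gave 0.66, 0.31 and 0.06.

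**Figure D3:**
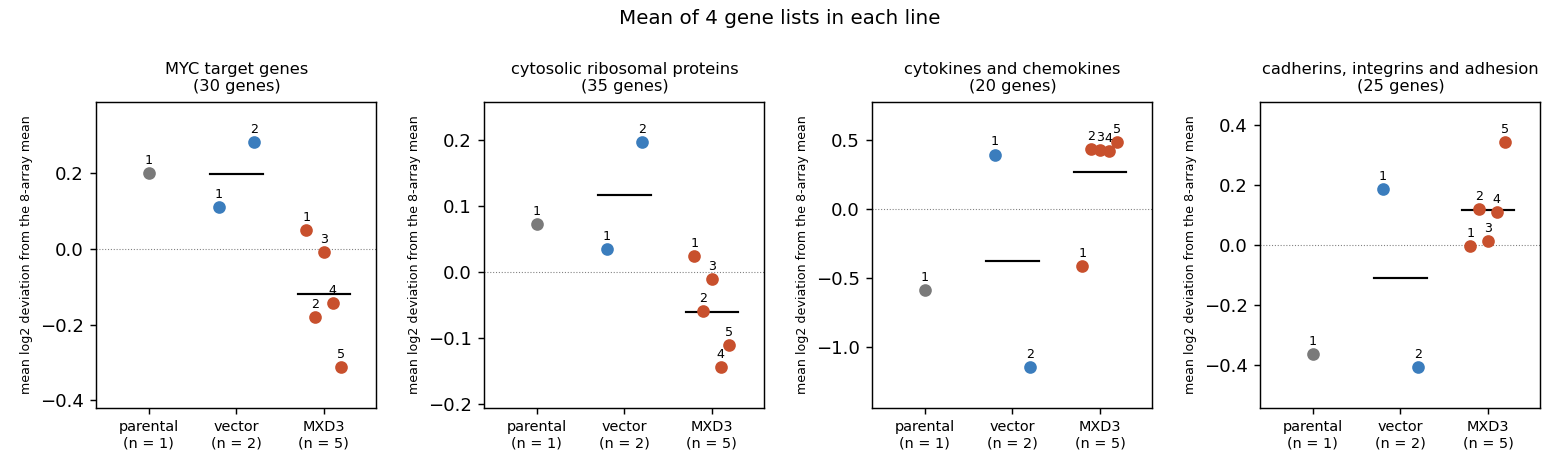
Mean log2 deviation from the 8-array mean over the genes of 4 lists in each line; points are single arrays numbered by line, horizontal bars are group means and the dotted line is 0. MYC target and ribosomal protein means of the 5 MXD3 lines lie below those of the 3 controls, while the cytokine mean of MXD3 line 1 (-0.41) lies apart from the other MXD3 lines and that of vector line 1 (0.39) apart from the other controls.

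Genes of adhesion and matrix differed member by member. Of 25 cadherin, integrin and adhesion genes, 19 had higher means in the MXD3 lines than in the vector and parental lines, with a mean log2 difference of 0.31 (adjusted p = 0.0384, camera, adjusted p = 0.652 with an estimated correlation). Against the vector lines the list was not called (0.23, adjusted p = 0.182), and without vector line 2 its means were 0.20 and -0.07. The integrin gene ITGA11 lay above all controls in 5 of 5 MXD3 lines, by 1.72 ± 0.32 (SE), and passed adjusted over the list alone (adjusted p = 0.0101) but not over all genes (adjusted p = 0.255). ITGA2 differed by 0.85 ± 0.31. Of 41 collagen and matrix genes, 26 had higher means and the list was not called (adjusted p = 0.251). COL13A1 (1.23 ± 0.34) and COL18A1 (0.84 ± 0.26) had positive differences, COL16A1 (-1.40 ± 0.43) and LUM (-1.40 ± 0.50) negative ones. COL8A1 was 1.42 ± 0.55 against the vector lines, 1 of which detected it, and 0.30 without vector line 2. Without that line COL18A1 was 0.50 against the vector and parental lines. LUM, which encodes lumican, was -2.07 ± 0.39 against the vector lines, where it passed adjusted over the list alone (adjusted p = 0.024). It was detected in 2 of 5 MXD3 lines and not in the parental cells, and was at least 3.63-fold higher in the vector lines than in the parental cells. The matrix protease gene PLAT differed by 1.10 ± 0.45, and by 0.62 without vector line 2.

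Over all 12162 genes, none passed limma's threshold in the MXD3 lines against the vector and parental lines. At an unadjusted p under 0.05 there were 1424 genes, 746 higher and 678 lower, where 608 were expected by chance. The smallest adjusted p was 0.247. Among the genes with the smallest p, all 5 MXD3 lines lay above all 3 controls for PDE10A (0.85 ± 0.13 SE), a phosphodiesterase gene, NTM (1.24 ± 0.20), which encodes the adhesion protein neurotrimin, the receptor phosphatase gene PTPRM (0.82 ± 0.16), ITGA11 and the phosphatase gene DUSP18 (0.71 ± 0.14). All 5 lay below all 3 controls for ITGB2 (-1.29 ± 0.19), an integrin subunit of leukocytes, the kinase gene STK32A (-0.95 ± 0.15), the laminin gene LAMC3 (-2.01 ± 0.32), GNAT2 (-1.08 ± 0.17), a transducin of cone cells, and the thiamine transporter gene SLC19A3 (-1.38 ± 0.23). ITGB2 was detected in 2 of the 5 MXD3 lines and SLC19A3 in 1, and both in all 3 controls. Genes whose MXD3 arrays and control arrays did not overlap numbered 970, 467 higher and 503 lower, or 7.98% against 3.57% by chance. Without MXD3 line 1, 1 gene passed, MAL2 (-1.83, adjusted p = 0.0413), named after its value was seen.

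Against the vector lines alone the count was also 0, with 942 genes at an unadjusted p under 0.05, 466 higher and 476 lower, where chance gives 608. The smallest adjusted p was 0.534. PDE10A (0.75 ± 0.13 SE), SLC67A1 (1.25 ± 0.24) and AAMDC (0.81 ± 0.16) had the smallest p among genes with higher means, with TOM1 and MYBL2, which were below detection in both vector lines and at least 1.36-fold and 1.57-fold higher in the MXD3 lines. MYBL2, a transcription factor gene of dividing cells, was 6.41 in the parental cells against 6.17 to 6.61 in the MXD3 lines. ITGB2 (-1.40 ± 0.21), CALCB (-2.27 ± 0.37), ROS1 (-1.48 ± 0.25) and PYGL (-0.97 ± 0.18), which encodes liver glycogen phosphorylase, had the smallest p among genes with lower means. DRC2, below detection in the MXD3 lines, was at least 1.11-fold lower. CALCB differed by -0.41 ± 0.49 between the MXD3 lines and the parental array and by 1.86 ± 0.55 between the vector lines and that array. ROS1, detected in 2 of 5 MXD3 lines, and DRC2 were below detection in the parental cells, and were at least 3.13-fold and 1.17-fold higher in the vector lines than there. TOM1 was 6.09 in the parental cells and 6.14 in the MXD3 lines, and SLC67A1 6.53 and 6.80. SLC67A1 was detected in 1 of the 2 vector lines, which read 5.98 and 5.12. Complete separation was seen in 1607 genes, 13.2% against 9.52% by chance.

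Cell cycle lists gave no uniform shift. Against the vector lines the 38 G2/M and mitosis genes were called lower (mean -0.13, 33 of 38 lower, adjusted p = 0.0498, camera, adjusted p = 0.868 with an estimated correlation). None had an unadjusted p under 0.05. Without MXD3 line 5, whose list mean was -0.43 against 0.04 to 0.21 in the other 4, the mean was -0.02 and the call ended (adjusted p = 0.747). Against vector and parental lines the mean was 0.00 (adjusted p = 0.908). Of 40 G1/S and DNA replication genes, 24 had higher means than in the vector and parental lines (mean 0.04, adjusted p = 0.908), among them CCNE2 (0.66 ± 0.24 SE), which encodes cyclin E2, and CHAF1B (0.32 ± 0.14). Of 8 genes of CDK inhibitors and the RB family, 7 had higher means (mean 0.26, adjusted p = 0.165), with CDKN1A at 0.78 ± 0.29 and CDKN2D at 0.51 ± 0.18. A further CDKN1A probe gave 0.22. TP53INP1, a p53 target, differed by 1.14 ± 0.33, while 9 of 23 p53 targets had higher means (adjusted p = 0.908). The apoptosis genes BAD (0.57 ± 0.16) and TRADD (0.32 ± 0.18) belonged to a list with 17 of 30 members higher (adjusted p = 0.301).

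Developmental pathways of medulloblastoma were not called against the vector and parental lines. In the Hedgehog list of 8 genes (adjusted p = 0.36), the transcription factor GLI2 differed by 0.52 ± 0.19 (SE), the receptor PTCH1 by 0.71 ± 0.29 and SMO by 0.40 ± 0.17. PTCH1 was below detection on the parental array, and differed by 0.34 ± 0.24 from the vector lines alone. In the WNT list 13 of 17 genes had higher means (mean 0.21, adjusted p = 0.161), with WNT5B at 0.89 ± 0.29 and the WNT antagonist RNF43 at -0.95 ± 0.36. The WNT list mean lay above all 3 controls in 5 of 5 MXD3 lines (exact permutation p = 0.0357, adjusted 0.321). MXD3 line 1 (-0.019) and vector line 1 (-0.044) lay close. That exact p was under 0.05 for 4 lists (MYC targets, ribosomal proteins, cytokines and WNT), and for 0 after adjustment. RNF43 was detected in 2 of 5 MXD3 lines, and read 7.16 in vector line 2 against 6.02 in vector line 1 and 6.24 in the parental cells. BMP7 was at -0.72 ± 0.20 and INHBA at 0.35 ± 0.16 in the BMP and TGF-beta list (adjusted p = 0.908), and HES4 at 0.41 ± 0.16 and HEY2 at 0.35 ± 0.17 in the NOTCH list (adjusted p = 0.634). HES5 was below detection in the 3 controls and at least 1.28-fold higher in the MXD3 lines, 4 of which detected it.

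Markers of other cell types gave no call in either comparison. Against vector and parental lines the adjusted p was 0.908 for the neuronal, glial and blood and endothelial lists, 0.165 for neural stem and granule precursor markers and 0.301 for epithelial markers. TUBB3, a neuronal tubulin, differed by -0.40 ± 0.17 (SE), OLIG1 by -0.58 ± 0.19, SOX9 by 0.74 ± 0.33 and PDGFRA by 0.77 ± 0.35. EPCAM was detected in 1 of 5 MXD3 lines, and PDGFRA in 1 of the 2 vector lines. Against the vector lines alone SOX9 differed by 0.485 ± 0.36.

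The parental array differed from all stable lines in 1 transcript past the threshold. The probe for 28S ribosomal RNA (RNA28SN5) read 11.40 in the parental cells, 14.61 in the vector lines and 14.69 ± 0.21 (SD, n = 5) in the MXD3 lines. Its log2 difference was 3.21 ± 0.25 (SE) for the vector lines (adjusted p = 0.009) and 3.28 ± 0.22 for the MXD3 lines (adjusted p = 0.00302). At an unadjusted p under 0.05 there were 864 genes for the vector and 1567 for the MXD3 lines. Leaving out either vector line ended the vector call (adjusted p = 0.13 without line 1 and 0.0585 without line 2), with fewer arrays but as large a difference, since the vector lines read 14.63 and 14.59. Across genes, which are not independent replicates, the parental array's deviation from the other arrays correlated with the span of the gene (Spearman's rho = -0.174, against -0.01 to 0.12 in the 7 stable lines), with genes of long span lower.

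On that array the G2/M and mitosis genes were lower than the mean of either kind of stable line, although MXD3 line 5 (list mean -0.43) lay below it (-0.27). They were higher in the vector lines by a mean of 0.41 (34 of 38 members, adjusted p = 2.3e-06, camera, adjusted p = 0.871 with an estimated correlation) and in the MXD3 lines by 0.27 (31 of 38, adjusted p = 0.0171, adjusted p = 0.698 with an estimated correlation). The proliferation marker MKI67 differed by 1.35 ± 0.35 (SE) between vector and parental lines, and the spindle genes TPX2 by 0.88 ± 0.27 and KIF11 by 0.72 ± 0.26. G1/S and DNA replication genes had a mean of -0.20 in the vector lines against the parental array (28 of 40 lower, adjusted p = 0.0109, adjusted p = 0.754 with an estimated correlation). Interferon response genes had a mean of 0.29 there (20 of 28 higher, adjusted p = 0.0418, adjusted p = 0.754 with an estimated correlation). MYC targets had a mean of -0.32 in the MXD3 lines against the parental array (24 of 30 lower, adjusted p = 0.000298, adjusted p = 0.598 with an estimated correlation).

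By the median of pairs, MXD3 lines differed from each other in fewer genes than from the parental array or from the vector lines, the latter through vector line 2. Counting genes more than 1 apart on the log2 scale, MXD3 lines 1 to 5 lay 170, 539, 325, 417 and 556 genes from the vector mean, and the parental array 368. The 2 vector lines differed from each other in 507 genes, a count between single arrays and not against a mean. Pairs of MXD3 lines differed in 297 to 679 genes (median 494.5, 10 pairs), MXD3 with vector lines in 305 to 867 (median 571.5, 10 pairs), MXD3 lines with the parental array in 468 to 1099 (median 946, 5 pairs) and vector lines with the parental array in 525 and 609. The ranges overlapped. These counts describe single arrays and carry no test.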

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

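The tests of gene span, array brightness, MYC level, dividing cells and shuffled gene order were chosen after the results were seen. Among the 5 MXD3 lines, 155 measures were checked for 1 line far from the others, and 10 had one, where chance gives about 1 in 20.

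MXD3 line 1 lay apart in the mean of the cytokine and chemokine list (-0.414, against 0.416 to 0.482 in the other lines), in IL1B (log2 6.78, against 9.62 to 10.3), in CKS2 (14.53, against 14.16 to 14.21) and in the mean of the G1/S and DNA replication list (-0.102, against 0.021 to 0.065). MXD3 line 5 lay apart in the mean of the G2/M and mitosis list (-0.429, against 0.039 to 0.21) and in PLK1 (9.13, against 9.69 to 9.90). MXD3 line 4 lay apart in HSPA4 (11.67, against 12.08 to 12.17), in RPL13 (11.58, against 11.83 to 11.93) and in the mean of the blood and endothelial marker list (-0.371, against 0.001 to 0.137). MXD3 line 2 lay apart in HERC5 (11.36, against 10.65 to 10.82). Of the probes without a gene symbol, which no comparison above used, 1 of 1431 passed limma's threshold in the MXD3 lines against vector and parental lines (log2 difference -1.54, adjusted p = 0.0248 over these probes alone); tested together with the named genes, none of them passed.

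For the MXD3 lines against the vector and parental lines, other splits of the 8 arrays into 5 and 3 were counted. The real split gave 0 genes past the threshold, a count that all 56 splits reach by construction, so it tests nothing (highest other 8). It gave 1424 genes at an unadjusted p under 0.05, a count that 3 of the 56 splits reached (highest other 1721), and 970 genes without overlap, which 3 of the 56 reached (highest other 1168). It gave 4 lists called by camera, which 27 of the 56 splits reached (highest other 13). Chance can therefore not be excluded for these 3 counts. The splits above the real one in genes set MXD3 lines 2, 4 and 5, or MXD3 line 1 with vector line 2 and the parental array, against the rest, so the arrays have a structure that the groups do not follow.

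Of 3 patterns weighed, the first is the lower MYC target list, whose median log2 difference of -0.321 lay at percentile 0 of 10000 random lists of the same brightness, whose central range was -0.0761 to 0.0854, which argues against a shift of bright genes in general. Less MYC transcript is argued against by MYC itself, at 0.549 ± 0.146 (SE). Fewer dividing cells remain open: G1/S genes lay 0.355 above MYC targets in the MXD3 lines relative to controls, but the exact permutation p was 0.0536. Repression by MXD3 was not tested. Looked at afterwards, the real split was the only 1 of 56 with an adjusted p as small as 4.23e-09 (camera) for this list. The split of MXD3 lines 2, 4 and 5 from the rest gave 9.88e-09. Camera called the list in many other splits as well. Setting MXD3 lines 1, 2 and 5 against the rest gave 6.41e-07, and MXD3 lines 3, 4 and 5 gave 1.97e-06. A call of this list by camera was therefore not particular to the real split.

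The second is the parental array standing apart, in its ribosomal RNA probe and in its trend with gene span. Across all genes it had the largest SD of deviation (0.437) and the lowest mean r with the other arrays (0.9762). MXD3 line 5 came close in both (0.425 and 0.9768), so these measures do not set the parental array apart. The parental array's deviation followed gene span (rho = -0.174), outside the range of the 7 other arrays (-0.00691 to 0.115). That was the outcome set for RNA quality or labelling of that sample. Gene span is not the length of the transcript, and no measure of RNA quality was tested, so this value cannot decide on that cause. For brightness of the array, rho with mean log2 intensity was -0.00129, within the range of the others (-0.0116 to 0.0339). Quantile normalization had already given all arrays the same distribution of intensities. Little such trend could remain in any array, so this value cannot decide on brightness. With 1 parental array, the sample and a true difference between parental and transfected cells remain open together.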

How the results depend on the processing

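Across the alternatives, all set before the data were examined, MYC targets stayed lower and called, from -0.401 to -0.231 against vector lines and from -0.361 to -0.269 against vector and parental lines, apart from the estimated correlation and fry. The line-number block among them compared only the lines whose number occurs in both groups. MXD3 itself kept its sign (0.143 to 0.616 and 0.22 to 0.693) and its side of the threshold. Of 230 pairs of a gene named from the main results with a comparison of the MXD3 lines against vector lines or vector and parental lines, none passed in any setting. MAL2, named because of a setting, passed against vector and parental lines without MXD3 line 1 (-1.83, adjusted p = 0.0413). Except where construction shows it, the cause was not tested. Where 1 vector line was left, it was assumed to vary like the other groups. Where a gene was below detection in a whole group, the signal over background allowed only a lowest fold.

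Called lists numbered 5 against vector lines and 4 against vector and parental lines. Both counts were 0 with an estimated correlation and 0 with the directional test of fry. Its mixed test passed 0 lists in the first and 2 in the second, the MYC, MAX and MXD family and hypoxia. The first was 2 with no filter, 3 with array weights, 3 with the MXD3 and vector arrays alone and 2 to 6 with 1 array left out. The second was 7 with detection on all arrays and 1 to 8 with 1 array left out. Genes past the threshold between MXD3 and parental lines, 1 in the report, were 3 with normexp without controls, 3 without background correction, 2 with the series matrix, 6 with detection on all arrays and 2 with trend and robust settings. With 1 array left out, genes numbered 0 to 1 against vector and parental lines and 0 to 1 between vector and parental lines.

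Distances from the vector mean (median of MXD3 lines 417, parental 368, vector lines apart 507) were 160, 118 and 198 with normexp without controls, 115, 66 and 140 without background correction and 898, 826 and 1060 with the series matrix.

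With 1 array left out, 47 of 115 named genes moved by over 1.5 times or changed sign against vector lines and 39 of 115 against vector and parental lines. Signs turned as follows. Against vector lines, the ranges were -0.126 to 1.41 for the cytokine list, -0.0709 to 0.524 for adhesion, -0.0119 to 0.981 for SOX9, -0.853 to 0.79 for PTPRC, -0.346 to 0.125 for MT1X, -0.00519 to 2.56 for CCL2, -0.0184 to 0.218 for MKI67 and -0.0984 to 0.0596 for TPX2. Against vector and parental lines, they were -0.131 to 0.112 for G2/M, -0.922 to 0.792 for STMN2 (0.258 with the series matrix), -0.706 to 0.403 for PTPRC, -0.0171 to 0.26 for MAGEA2 and -0.0306 to 0.407 for TPX2. The brightest probe of a gene was picked anew in each setting, and PTPRC turned with a change of probe. On its main probe the MXD3 lines read 4.99 to 6.08 and the vector lines 6.15 and 6.14. Another PTPRC probe gave 0.549 against vector lines and 0.372 against vector and parental lines. This change of probe also enters the counts of genes that moved.

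With the line number as a block for pairing, 1 list was called against vector lines, MYC targets (-0.262), 0 genes passed, and TPX2 was 0.105. This contrast rested on lines 1 and 2 of each kind alone. The other MXD3 lines share no number with a vector line and added nothing to it. Deviations of arrays sharing a number correlated at -0.309 and -0.179. With 2 vector lines, the deviations from their mean mirror each other, so these values cannot show whether the numbers pair arrays. A chip block was not run.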

Other observations

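The tests of shuffled gene order were chosen after the runs were seen; the share of genes on one side was fixed before it was computed.

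Camera called none of the stress and metabolic lists, and single members stood apart. The mixed test of fry, for changes in either direction, passed for the hypoxia list against the vector and parental lines (adjusted p = 0.00611). Against the vector and parental lines, the hypoxia-linked carbonic anhydrase gene CA12 was lower in 5 of 5 MXD3 lines, by -1.35 ± 0.23 (SE), and passed adjusted over the list alone (adjusted p = 0.00369) though not over all genes (adjusted p = 0.247). DDIT4, another member of the 21 hypoxia genes (list adjusted p = 0.499), differed by -0.88 ± 0.26. The heat shock list had 10 of 15 members lower (adjusted p = 0.165), with HSPA4 at -0.56 ± 0.15 and the mitochondrial chaperone HSPE1 at -0.36 ± 0.13. PPP1R15A, a gene of the unfolded protein response, differed by 0.71 ± 0.22 and CTH by -0.52 ± 0.24 (list adjusted p = 0.767). The glycolysis gene PFKL was at 0.57 ± 0.18 and ALDOC at -0.62 ± 0.20 (list adjusted p = 0.634), and the metallothionein MT1G at -1.11 ± 0.37 (list adjusted p = 0.393). Of 22 immediate early genes 16 had higher means (mean 0.28, adjusted p = 0.0572), with IER3 at 0.81 ± 0.33 and KLF6 at 0.49 ± 0.19. Against the vector lines alone KLF6 was at 0.30 ± 0.19. The NRF2 list (adjusted p = 0.305), cholesterol synthesis (0.908), replication-dependent histones (0.908), the respiratory chain (0.994), cancer-testis antigens (0.908), angiogenesis factors (0.94), matrix proteases (0.213) and HOX genes (1) were not called.

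Genes of immune recognition had values in both directions. Antigen presentation was called against the vector lines (mean 0.14, 9 of 11 higher, adjusted p = 0.0498, camera, adjusted p = 0.855 with an estimated correlation) and not against vector and parental lines (adjusted p = 0.0572). The first call held in 8 of 19 alternative settings, with a mean from 0.03 to 0.24 and an adjusted p up to 0.386. TAP1 (0.36 ± 0.13 SE), TAP2 (0.42 ± 0.15) and HLA-F (0.48 ± 0.17) had positive differences from the vector and parental lines. A second TAP2 probe gave 0.23, and -0.05 against the vector lines alone. TAPBP was at 0.83 ± 0.22 by the probe used (0.53 ± 0.17 against the vector lines alone), and at 0.15 and -0.07 by its 2 other probes. The interferon response list was not called (adjusted p = 0.908), and its member IFI44L was at -1.89 ± 0.35 against the vector lines, where it passed adjusted over the list alone (adjusted p = 0.0151). IFI44L differed by -0.40 ± 0.46 between MXD3 lines and the parental array and by 1.49 ± 0.51 between vector lines and that array.

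Single stable lines had runs of neighbouring genes shifted together, the third pattern: over 31 neighbouring measured genes the largest mean deviation from the median of the other arrays was 0.708 in MXD3 line 5 (TPBG to BACH2), -0.655 in vector line 2 (CHST12 to BZW2) and -0.595 in MXD3 line 2 (SH3GL3 to IDH2). The largest run of the parental array was -0.382 (PCDHA2 to RNF14), which 16 of 1000 shuffles reached. Those of MXD3 lines 1 and 3 both lay on chromosome 2 (-0.379 and 0.37). Those of vector lines 1 and 2 both lay on chromosome 7 (0.372 and -0.655). Chance arrangement is argued against, since 1000 shuffles of gene order reached the largest mean in 0 of the 7 stable lines. A few clusters of similar genes remain undecided, although 96.8% of the genes of the largest run lay on its side, past the 75% set beforehand. That bound was poorly chosen, because shuffled runs had a median of 71%, and the outcome was set to undecided after this was seen, although only 1 of 1000 shuffles leaned as far in MXD3 line 5 and 0 in vector line 2 (302 in MXD3 line 1). Gains or losses in the DNA of single lines may underlie the runs, as a hypothesis that was not tested here.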
